A study of Homo sapiens with 18 samples.

How the data were processed

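PolyA RNA of 18 samples of the human embryonic stem cell line H1 was sequenced, per the labels. The labels give each sample's genotype (parental or ZNF263 knockout), its lineage and a replicate number from 1 to 3. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made with NEBNext poly(A) selection and Ultra II kits. The submitters' processing notes name STAR, featureCounts, DESeq2 and the genome build hg19, without versions. The deposited values are raw counts per gene, whole numbers with no normalization, in a table of 12 mesoderm and ectoderm libraries and a table of 6 endoderm libraries. Both tables hold the same 27130 genes under the same names and with the same coordinates. The strand setting of the counting is not given in the sources used here, so reads of a gene and of an overlapping or antisense gene cannot be told apart. The treatment of reads that match several places is not given either. Such reads can be lost or split between pseudogenes and near-identical copies.

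Columns were assigned to samples by their names. The knockout columns carry another line number (2-10) than the sample titles (1-10). They were assigned because each lineage has 1 edited line in the labels and 1 set of columns that is not parental, and this mapping rests on that. No value column was left without a sample. Replicate pairs were compared by a chi-square test over genes, and no pair agreed within sampling noise (chi-square per degree of freedom 2.66 to 80.95). Coordinates are those of the deposited tables (hg19). A gene on 1 chromosome and on alternate haplotype sequences was given the chromosome's coordinates.

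The main test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM normalization, the default filterByExpr filter (minimum count 10 and minimum total 15), robust dispersion estimates and Benjamini-Hochberg adjustment. Each lineage was fitted alone for KO against WT. WT mesoderm was compared with WT ectoderm over their 6 libraries. The interaction of mesoderm and ectoderm was fitted over 12 libraries and those with endoderm over 18. A gene was called at an adjusted p under 0.05. The SE of a log2 change is its size divided by the square root of the test's F value. All group means are of CPM with TMM-adjusted library sizes. The floor for a group at 0 is 3 counts over the group, and counting intervals are at 95% and cover counting error only, since PCR copies were not identified.

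Before the data were examined, 39 gene lists were fixed, along with the design and the alternatives. Lists with at least 5 tested members were tested with camera of limma 3.58.1, at a preset correlation of 0.01. That gave 38 lists in mesoderm and in ectoderm and 37 in endoderm. Camera with an estimated correlation and fry were alternatives. Of the 10, 26 and 14 lists that passed in mesoderm, ectoderm and endoderm, 1, 4 and 0 passed with an estimated correlation. A list of mitochondrially encoded mRNAs had no member in the tables, so it was void.

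The genes named in the text were chosen by a rule fixed at the same time. It took ZNF263 and, per KO comparison, the 8 largest increases and 8 largest decreases with an adjusted p under 0.05, a mean log2 CPM of at least 1 and no overlap between the libraries of the groups. It added up to 4 called members per list by size of change. For interactions it took 4 genes per direction without the condition on overlap, and for WT mesoderm against WT ectoderm up to 4 called members per lineage list. Clone-based names, names that begin with LINC, MIR or SNOR, XIST and Y-linked genes were left out. Numbered names that begin with LOC were kept. Not every gene that the rule gives is named in the text. Genes named as changed in all lineages and those named in the closing section outside this rule were chosen after their values were seen.

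The scripts were tested on simulated counts with 200 changed genes. In the mesoderm simulation over 15062 genes, 78% of 1.5-fold changes and 88% of 2-fold changes were recovered. In the ectoderm simulation over 17532 genes these were 82% and 88%, and in the endoderm simulation over 16490 genes 24% and 88%. At 1.25-fold the shares were 34% in mesoderm, 66% in ectoderm and 6% in endoderm. Changes of 1.5-fold or less in endoderm were therefore mostly not detectable, and the biological coefficient of variation was 13.5% there against 7.29% in mesoderm and 4.01% in ectoderm.

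Alternatives were DESeq2 size factors within edgeR, library totals only, no low count filter, the Wald test of DESeq2 1.42.0, no robust estimation, an added 2-fold criterion, leaving out each library, a replicate block, a fit over further groups and leaving out mitochondrial genes. A GC correction was added after the data were seen. It enters as an offset a smoothing spline per library, with 5 degrees of freedom, on the GC content of the longest GENCODE transcript with the gene's symbol. The spline was fitted to the deviation of the library's log2 CPM from the gene's mean over the libraries fitted. Symbols matched for 24732 of 27130 genes (91.2%), and for at least 95.5% of the genes tested in each lineage. Figures were drawn with matplotlib.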

Results

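The series holds polyA RNA-seq of H1 (WA01), an established human embryonic stem cell line, as the parental line (WT) and as an edited line in which ZNF263 was knocked out (KO). ZNF263 encodes a zinc finger protein of the KRAB-SCAN family. Cells of both genotypes had been taken toward mesoderm, ectoderm or endoderm, the embryonic germ layers, which gave 6 groups of 3 libraries and 18 libraries in all. Total gene counts per library ranged from 16512972 to 17214755 in WT mesoderm and from 15937000 to 35249327 in KO mesoderm. They ranged from 36721128 to 57532055 in WT ectoderm and from 43389512 to 49452217 in KO ectoderm. In endoderm they ranged from 17147092 to 34831612 in WT and from 20266370 to 32299532 in KO. Levels are given in CPM, counts scaled to a common library total within each lineage, as means ± SD over the 3 libraries of a group. The sources do not say whether the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The labels name 1 edited line, so a difference between KO and WT is a difference between these lines.

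The targeted gene was examined first. ZNF263 (hg19 chromosome 16, 3333487 to 3341459, plus strand) was still transcribed in the KO line, at a lower level in each lineage. In mesoderm it lay at 34.5 ± 0.66 CPM in WT and 27.0 ± 0.85 in KO, a log2 change of -0.35 (SE 0.09, edgeR adjusted p = 0.00175). In ectoderm it lay at 35.7 ± 1.4 CPM in WT and 28.8 ± 0.71 in KO, a log2 change of -0.31 (SE 0.05, edgeR adjusted p = 4.52e-05). In endoderm the values were 36.0 ± 3.3 and 26.9 ± 1.4 CPM, and the difference did not pass the threshold (log2 change -0.42, SE 0.11, edgeR adjusted p = 0.123). The KO libraries lay below the WT libraries of their lineage in all lineages. Within a single lineage, chance gives such a separation, in either direction, in 10% of comparisons of 3 libraries with 3. The share for the same direction in all lineages together was not computed. The position of the edit is not given in the sources used here, so whether these reads come from an altered transcript was not analysed here.

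**Figure D1:**
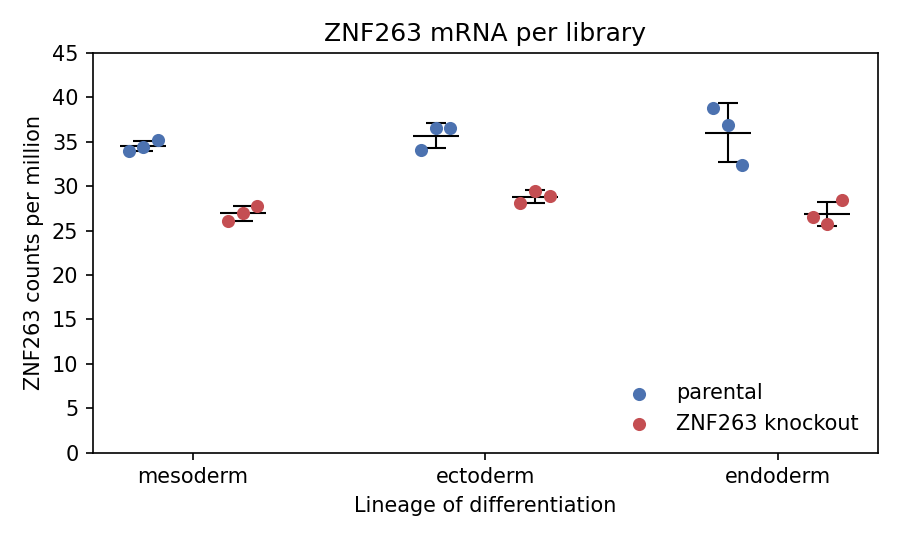
ZNF263 level in CPM (y axis) in each of the 18 libraries, by lineage (x axis) and genotype; points are libraries, and black bars are the mean and SD of 3 libraries. The KO means of 27.0, 28.8 and 26.9 lie below the WT means of 34.5, 35.7 and 36.0.

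WT mesoderm was compared with WT ectoderm to place the samples by the lineage genes they expressed. Of 17 primitive streak genes, 11 were higher in mesoderm and 4 in ectoderm, and of 15 genes of paraxial mesoderm, which forms the somites, 11 were higher in mesoderm and 3 in ectoderm. MIXL1 and TBXT, transcription factors of the streak, were 1110-fold and 350-fold higher (827 ± 69 against 0.794 ± 0.28 CPM, and 313 ± 18 against 0.947 ± 0.19 CPM). The folds come from the joint fit of the WT libraries, while the CPM were scaled within each lineage, so they need not match exactly. HES7, an oscillating repressor of the somite clock, was 161-fold higher. Neuroectoderm genes were higher in ectoderm for 28 of 31 tested members and neuronal genes for 20 of 24. SOX2, a factor of neural and pluripotent cells, lay at 428 ± 7.9 CPM in ectoderm and 0.817 ± 0.09 in mesoderm. MAP2, a neuronal cytoskeletal protein, lay at 436 ± 16 and 2.58 ± 0.62 CPM. All 31 tested HOX genes were higher in mesoderm. The edgeR quasi-likelihood test called 12630 of 16708 genes at an adjusted p under 0.05, with 6128 higher in mesoderm and 6502 higher in ectoderm.

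In mesoderm, targets of p53 were higher in KO than in WT, and genes of cholesterol synthesis and of S phase were lower. Library measures also differed by genotype in this lineage without overlap, an order that chance gives in 10% of such comparisons. The 2 genes of the mitochondrial chromosome took 0.703% to 0.840% of counts in KO and 0.497% to 0.552% in WT, and the 10 genes with the most counts took 4.97% to 5.04% in KO and 3.96% to 4.10% in WT. Of 23 tested p53 targets, 20 rose, 7 of them at least 2-fold, and none fell. The mitochondrial quality gene SPATA18 rose from 5.27 ± 0.48 to 22.3 ± 1.6 CPM, the cytokine gene GDF15 from 2.61 ± 0.37 to 10.8 ± 0.94, and CDKN1A, which encodes the cell-cycle inhibitor p21, from 32.4 ± 3 to 98.4 ± 10.2. Of 24 cholesterol synthesis genes, 19 fell and none rose. LSS, lanosterol synthase, fell from 293 ± 22 to 143 ± 19 CPM. Of 24 S phase genes, 20 fell and 1 rose, with CDC45 down 1.58-fold and FEN1 down 1.55-fold. In the list of hypoxia and glycolysis genes 13 fell and 8 rose. Its largest decreases were in hexokinase 2 (HK2, 155 ± 10.5 to 28.8 ± 1.8 CPM) and the glucose transporter SLC2A1 (414 ± 13 to 114 ± 8.3 CPM). Paraxial mesoderm genes fell for 6 of 13 members and rose for 2. RSPO3, a WNT agonist, fell 2.36-fold and HES7 fell 2.03-fold. Of 79 ribosomal protein genes, 52 rose and 2 fell, by small amounts (RPLP0 rose 1.33-fold). In the lateral plate and cardiac list 6 of 19 genes rose and 3 fell, among them ACTC1, cardiac actin, up 2.66-fold. That list as a whole did not pass camera (adjusted p = 0.239), and its median log2 change was -0.02 while camera put its direction upward.

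The lists were tested against all other genes with camera at a preset correlation. Camera compares the members' statistics for KO against WT with those of the other genes, not the counts of called members. The p53 targets passed (adjusted p = 2.81e-17) and did so with an estimated correlation (adjusted p = 0.0415 with an estimated correlation). Cholesterol synthesis passed at 1.23e-13 (adjusted p = 0.0835 with an estimated correlation). S phase passed at 2.22e-07 (adjusted p = 0.151 with an estimated correlation). Ribosomal proteins passed at 4.36e-06 (adjusted p = 0.239 with an estimated correlation). Hypoxia and glycolysis passed at 0.000112 (adjusted p = 0.381 with an estimated correlation). Imprinted genes passed at 0.00247 and paraxial mesoderm at 0.00699 (adjusted p = 0.171 and 0.635 with an estimated correlation). Interferon response genes were lower for 11 of 23 members and higher for 3 (camera adjusted p = 0.0259, adjusted p = 0.552 with an estimated correlation). YAP targets rose for 8 of 17 members and fell for 2 (camera adjusted p = 0.033, adjusted p = 0.301 with an estimated correlation). Amnion and trophoblast genes rose for 4 of 7 members (camera adjusted p = 0.033, adjusted p = 0.531 with an estimated correlation). Adjusted over the list alone, the counts were 20 higher of the p53 targets, 20 lower of the cholesterol genes and 21 lower of the S phase genes.

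The largest single changes in mesoderm had other identities. ZNF558, a KRAB zinc finger gene (hg19 chromosome 19, 8920252 to 8942980), was at 16.5 ± 1.6 CPM in WT and had 0 counts in the KO libraries, at least 387-fold lower against a floor of 3 counts over the group. ZNF596 (hg19 chromosome 8, 182137 to 197340) had 0 counts in WT and lay at 3.55 ± 0.67 CPM in KO, at least 56.5-fold higher. The imprinted noncoding RNA gene H19 (hg19 chromosome 11, 2016406 to 2022696) rose from 0.179 ± 0.1 to 60.4 ± 3.2 CPM. The pseudogene HSD17B7P2 rose from 0.158 ± 0.089 to 15 ± 0.6 CPM and RPL23AP53, which overlaps ZNF596 on the map, from 0.139 ± 0.068 to 5.33 ± 0.31. Reads of both pseudogenes can be split with near-identical copies, and their values are uncertain for that reason. S100A6, a calcium-binding protein gene, fell from 22.2 ± 0.59 to 2.46 ± 0.4 CPM and TCEAL5 from 7.68 ± 0.63 to 0.404 ± 0.16. The edgeR quasi-likelihood test called 6328 of 15062 genes at an adjusted p under 0.05, with 3067 higher and 3261 lower in KO. Most changes were small: 851 of these genes changed at least 2-fold, 488 upward and 363 downward.

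In ectoderm, genes of pluripotency, of Nodal signalling and of the primitive streak were higher in KO, and neuroectoderm genes were lower. Of 25 primed pluripotency genes, 19 rose and 5 fell. All 8 members under 5 CPM in WT rose, and of the 17 at 5 CPM or more in WT, 11 rose and 5 fell. NANOG rose from 0.218 ± 0.051 to 2.96 ± 0.25 CPM, POU5F1 from 0.638 ± 0.067 to 3.72 ± 0.24, and the Nodal co-receptor gene TDGF1 from 2.81 ± 0.29 to 22.3 ± 1.04. Of 15 Nodal and Activin targets, 10 rose, 9 of them at least 2-fold, and 1 fell. The streak list had 14 of 19 genes higher and 1 lower, with EOMES up 5.65-fold and MIXL1 up 6.49-fold (0.794 ± 0.28 to 5.05 ± 0.32 CPM). Of 32 neuroectoderm genes, 24 fell and 3 rose. PAX6, a master regulator of eye and forebrain (hg19 chromosome 11, 31806340 to 31839509), fell from 165 ± 12 to 53 ± 1.9 CPM and the forebrain factor FEZF2 from 6.62 ± 0.39 to 2.22 ± 0.34. HES3, a repressor of the HES family in the same list, rose from 5.33 ± 0.62 to 14.9 ± 0.81 CPM. Neuronal genes fell for 12 of 24 members and rose for 4, with NEUROD4 down 2.24-fold. The homeobox gene BARHL1, outside those lists, was among the largest decreases (71.7 ± 3.7 to 17 ± 0.9 CPM).

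Members of other lists, some of them written for other cell types, also moved in KO ectoderm. Their changes do not show that such cells were present. Of 23 amnion and trophoblast genes, 18 rose and 1 fell. CGA, the common alpha subunit of glycoprotein hormones, rose from 1.03 ± 0.35 to 16.0 ± 5.7 CPM, and CGB5, a chorionic gonadotropin beta subunit, had 3 counts in WT and 151 in KO, a ratio of 47.0 (95% counting interval 15.8 to 231). CGB5 and CGB8 are near-identical copies whose reads can be split between them. Surface ectoderm and placode genes rose for 16 of 20 members, among them the epithelial adhesion genes EPCAM (2.06-fold) and CDH1 (1.80-fold). Of 24 interferon response genes, 23 rose and none fell, by under 2-fold each, with IFIT1 up from 899 ± 41 to 1440 ± 37 CPM and ISG15 from 945 ± 63 to 1480 ± 20. Clustered protocadherin genes, which encode neuronal adhesion proteins, fell for 27 of 53 members and rose for 2.

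In camera, 26 of 38 lists passed in ectoderm, 19 upward and 7 downward. Primed pluripotency (adjusted p = 1.89e-30), neuroectoderm (4.54e-23), Nodal and Activin targets (7.69e-20) and interferon response (4.27e-40) also passed when the correlation was estimated (adjusted p = 0.0186, 0.0186, 0.0202 and 0.0186 with an estimated correlation). The primitive streak list passed at 5.75e-18 (adjusted p = 0.057 with an estimated correlation) and neurons at 0.000443 (adjusted p = 0.0691 with an estimated correlation). Surface ectoderm passed at 2.97e-13 and amnion and trophoblast at 1.2e-10 (adjusted p = 0.129 for each with an estimated correlation). Clustered protocadherins passed at 3.36e-06 (adjusted p = 0.244 with an estimated correlation). Adjusted over the list alone, 24 neuroectoderm genes were lower and 4 higher, 19 pluripotency genes higher and 5 lower, and 24 interferon response genes higher. The edgeR test called 6188 of 17532 genes, with 3290 higher and 2898 lower in KO, and 425 of them changed at least 2-fold, 297 upward and 128 downward. The balance of all calls turned with the GC correction, which gave 3393 higher and 4330 lower. ZNF558 fell from 26.3 ± 1.6 to 0.177 ± 0.013 CPM, H19 rose from 1.85 ± 0.51 to 140 ± 1.9 CPM, and ZNF596 from 0.0913 ± 0.058 to 5.97 ± 0.62 CPM.

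In endoderm, 179 genes passed, and the list with the most called members was neuroectoderm, at lower levels in KO. Of 30 neuroectoderm genes, 10 fell, each at least 2-fold, and none rose. Adjusted over the list alone, 15 were lower. The eye-field genes SIX3 and RAX fell from 8.13 ± 2.1 to 1.92 ± 0.33 CPM and from 3.61 ± 1.4 to 0.550 ± 0.17 CPM, and FEZF2 from 2.96 ± 1.03 to 0.235 ± 0.16. Without KO endoderm replicate 1, RAX and FEZF2 did not pass (edgeR adjusted p up to 0.0679 and 0.0637), and SIX3 passed in every setting. Of the endoderm and streak genes, CER1, a secreted Nodal and BMP antagonist, fell 1.39-fold from 3140 ± 307 CPM, and MIXL1 fell 1.67-fold (135 ± 16 to 81.3 ± 0.25 CPM). EVX1, a homeobox gene of the streak, rose from 1.03 ± 0.59 to 5.24 ± 0.64 CPM, but its reads cannot be told from those of the antisense gene EVX1-AS. CER1 and MIXL1 did not pass without WT replicate 2 or without any 1 of the KO libraries (edgeR adjusted p up to 0.289 and 0.103). CER1 also did not pass with library totals only or with the replicate block, so it lost the call in 6 of 15 settings. EVX1 did not pass without KO replicate 1 (up to 0.0507). In the definitive endoderm list 2 of 25 genes fell and none rose. In the list of the integrated stress and unfolded protein response 3 of 21 genes fell, and adjusted over the list alone 14 did. Of 15 Nodal and Activin targets, 2 fell, and 10 did adjusted over the list alone. ZNF558 was at 4.67 ± 0.39 CPM in WT with 0 counts in KO, at least 132-fold lower. ECHDC3 fell from 15.9 ± 3.3 to 0.210 ± 0.029 CPM, S100A6 from 5.88 ± 0.84 to 0.200 ± 0.042, and the collagen gene COL3A1 from 5.98 ± 1.1 to 0.293 ± 0.12. ZNF596 had 2 counts in WT and 260 in KO, a ratio of 120 (95% counting interval 32.9 to 998).

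The edgeR test called 179 of 16490 genes in endoderm, with 73 higher and 106 lower in KO, and 104 changed at least 2-fold. Camera passed 14 of 37 lists, 10 downward and 4 upward, and with an estimated correlation 0 passed, while fry passed 5. For neuroectoderm the adjusted p was 6.83e-26 (adjusted p = 0.219 with an estimated correlation), for the stress response list 1.58e-12 and for Nodal and Activin targets 3.09e-08 (adjusted p = 0.219 for each with an estimated correlation). WT endoderm libraries differed more among themselves than other groups did, with a biological coefficient of variation of 17% against 3.33% to 8.26% in the other groups. The count of called genes moved with single libraries, from 41 without KO replicate 1, 47 without KO replicate 2, 63 without WT replicate 2 and 85 without KO replicate 3 to 425 without WT replicate 1. A correction for GC content, chosen after the data were seen, raised it to 991, and all 179 genes were among these in the same direction.

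**Figure D2:**
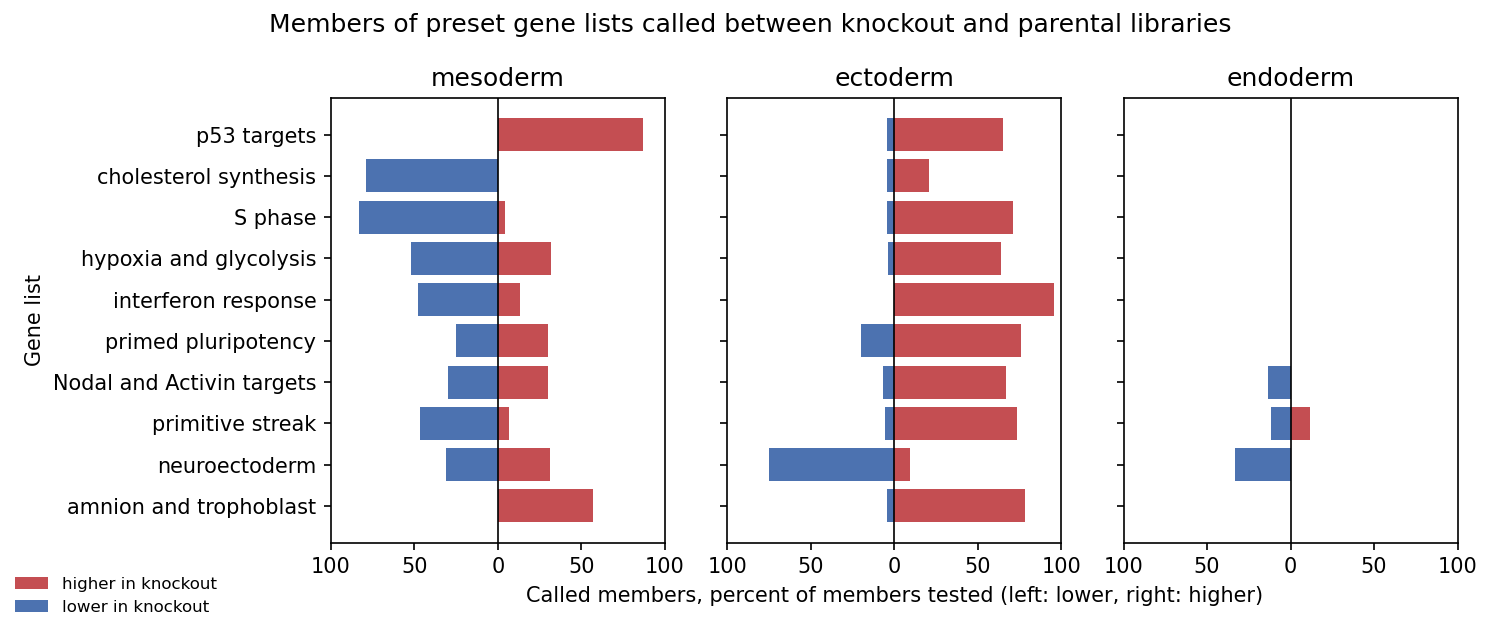
Percent of tested members of 10 gene lists (rows) called higher (right) or lower (left) in KO than in WT, in each lineage, by edgeR at an adjusted p under 0.05; the 10 lists were picked after the results were seen from the 39 preset ones. In mesoderm 20 of 23 p53 targets were higher and 19 of 24 cholesterol synthesis genes lower, and in ectoderm 23 of 24 interferon response genes were higher and 24 of 32 neuroectoderm genes lower.

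The difference of the KO effect between lineages was tested as an interaction. Between mesoderm and ectoderm, 6573 of 17834 genes had different effects, 3247 with a more positive change in mesoderm and 3326 in ectoderm. In each interaction a different effect can also mean that a gene was at low counts in 1 lineage. Only 14816 genes passed the count filter in both the mesoderm and the ectoderm fit. Of the 23 p53 targets, 16 changed more positively in mesoderm and 1 in ectoderm, where 15 of them also rose in KO and 1 fell (camera adjusted p = 5.07e-05, and adjusted p = 0.057 with an estimated correlation). All 19 cholesterol synthesis genes that differed, of 24 tested, changed more positively in ectoderm. The same held for 22 of 24 S phase genes, and for 18 of 24 interferon response genes against 1 the other way. Of 19 primitive streak genes, 14 changed more positively in ectoderm. Between endoderm and mesoderm 3160 of 18261 genes differed. Between endoderm and ectoderm 1070 of 18261 genes differed, with 750 more positive in ectoderm, which included 15 of 25 primed pluripotency genes and 11 of 15 Nodal and Activin targets. That count was 594 with the replicate block and 1871 without WT endoderm replicate 3. Both interactions with endoderm share 1 spread over the 18 libraries, though the biological coefficient of variation was 17% in WT endoderm and 3.33% to 8.26% in the other groups. The KO calls in endoderm rose from 179 to 1092 when the spread was shared in that way. The endoderm libraries also come from a separate table, so lineage and table cannot be told apart in these interactions.

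The genes called in each lineage were then compared. Of 14816 genes tested in both mesoderm and ectoderm, 1090 were called in the same direction, where independent lists would share 1150, and 1563 in opposite directions, where 1150 would be shared. Endoderm shared 67 genes of the same direction with mesoderm, against 29 from independent lists, and 98 with ectoderm, against 31.4. In all lineages together 51 of 14462 genes were called in the same direction, 27 higher and 24 lower, where independent lists would give 5.33. They included ZNF558, ZNF596, H19, HSD17B7P2, RPL23AP53, ECHDC3, NAP1L6, S100A6, TMEM119 and VSTM2L. The log2 change of TMEM119, a membrane protein gene, was 2.04 in mesoderm, 2.78 in ectoderm and 2.30 in endoderm. For the neural transcription factor gene ZIC1 it was -1.91, -1.22 and -2.90. For the zinc finger gene ZNF528 on chromosome 19 it was 1.81, 1.02 and 2.33. H19 did not pass in endoderm without KO replicate 2 (edgeR adjusted p up to 0.0502).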

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

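The results here were picked because the KO effect differed between lineages in a test of the difference itself, the edgeR interaction. The counts of other splits of the samples were planned before their results were seen. Groups of 3 libraries are too small for a test of single outlying samples. The limits of the shared spread and of the separate table, given above, hold for the interactions with endoderm here too.

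Between mesoderm and ectoderm 6573 genes differed. None of the 59 other splits drawn within the lineages reached that number (1 of 60 splits). The highest of them, 5870, exchanged KO and WT in 1 lineage alone. Splits that mix the genotypes within a lineage stand for no KO effect there, not for an equal effect in both lineages. They therefore cannot decide whether chance gave this count. In the interaction (log2 change in mesoderm minus that in ectoderm), genes chosen by the rule had positive values of 4.68 for BCO1, 3.76 for VSTM2L and 3.54 for INSM1. Negative values were -5.90 for POU4F1, -4.94 for ZNF558, -4.44 for LOC105374596 and -4.36 for FGF10-AS1. VSTM2L rose from 0.459 ± 0.074 to 8.88 ± 0.2 CPM in mesoderm and from 31.2 ± 1.3 to 44.7 ± 2.2 CPM in ectoderm. The values of the other genes here rest on a group with at most 3 counts in 1 lineage, so their size depends on the prior count and is no bound. BCO1 did not pass with DESeq2, without any 1 of the WT mesoderm libraries or without KO mesoderm replicate 2 or 3 (adjusted p up to 0.0729). LOC105374596 did not pass without KO ectoderm replicate 1 (adjusted p up to 0.0863). FGF10-AS1 is an antisense gene, whose reads cannot be told from those of its partner.

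Between endoderm and mesoderm 3160 genes differed. Of 60 splits 3 gave as many, the real one included, a share of 0.05, which reaches the planned threshold of 0.05. Chance is thus not excluded, but these splits cannot decide on it, for the reason given for the mesoderm to ectoderm interaction. The highest other split gave 4405 and exchanged KO and WT in 1 lineage alone, which adds the effects in place of subtracting them. The interaction (endoderm minus mesoderm) was 5.20 for POU4F1, 4.65 for EVX1-AS, 3.71 for TNNT2 and 3.38 for TCEAL5. It was -10.19 for SLC12A3, -5.82 for PRDM14 and -5.61 for GDF3. All of these but TCEAL5 rest on a group with at most 2 counts in 1 lineage, so their size is no bound, and EVX1-AS is an antisense gene. SLC12A3 and PRDM14 did not pass without KO mesoderm replicate 3 (adjusted p up to 0.125 and 0.148) and TCEAL5 did not without KO endoderm replicate 2 (up to 0.0518). TNNT2 did not pass without WT mesoderm replicate 3 or KO mesoderm replicate 1 or 3, or without the low count filter (up to 0.289). POU4F1 did not pass without any 1 of the mesoderm libraries, without KO endoderm replicate 1, without the low count filter or without robust estimation (up to 0.135). TCEAL5 fell from 7.68 ± 0.63 to 0.404 ± 0.16 CPM in mesoderm and lay at 0.177 ± 0.067 and 0.107 ± 0.083 CPM in endoderm.

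Between endoderm and ectoderm 1070 genes differed. Of 60 splits 2 gave as many, the real one included. The other split that did, at 2267, exchanged KO and WT in 1 lineage alone. As in the mesoderm to ectoderm interaction, the splits cannot decide whether chance gave this count. The interaction (endoderm minus ectoderm) was 2.63 for DMRT3, 2.58 for TCEAL5, 2.37 for PGM5 and 2.15 for DMBX1. It was -7.13 for SLC12A3, -5.64 for HOXA2, -5.46 for GDF3 and -5.44 for NKX6-1. GDF3, a Nodal-related ligand, rose from 0.0768 ± 0.0065 to 2.13 ± 0.19 CPM in ectoderm and lay at 16.0 ± 2.9 in WT and 9.73 ± 0.5 CPM in KO endoderm. SLC12A3, HOXA2 and NKX6-1 had 0 counts in KO endoderm, so their fitted values are no bound. HOXA2 did not pass without WT endoderm replicate 1 or 2 or KO endoderm replicate 1 or 3 (adjusted p up to 0.0784). TCEAL5 did not pass with the replicate block, without any 1 of the WT ectoderm libraries, KO ectoderm replicate 1 or 2, WT endoderm replicate 2 or 3, or KO endoderm replicate 2 or 3 (up to 0.287). The count of genes was 594 with the replicate block and 1871 without WT endoderm replicate 3.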

How the results depend on the processing

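The GC correction was added after the data were seen; all other settings were fixed before. No named gene, and no list that passed camera, reversed its direction in any setting. The 2-fold criterion was not applied to single genes. In the settings run for them, 361 of 422 named results outside ZNF263 kept the call throughout. The other 61 lost it in at least 1 setting: 30 in endoderm, 12 in ectoderm, 10 in mesoderm and 9 in the interactions. In ectoderm the calls were 3290 higher and 2898 lower, and 3393 higher and 4330 lower with the GC correction. The counts of called genes in mesoderm, ectoderm, WT mesoderm against WT ectoderm and the mesoderm to ectoderm interaction stayed within 1.5 times under every setting but the 2-fold criterion, which by its construction left 851, 425, 4979 and 1384 genes. It left 104 genes in endoderm, 914 in the endoderm to mesoderm interaction and 402 in the endoderm to ectoderm interaction. In endoderm 179 genes became 316 without the low count filter, 444 with the DESeq2 Wald test, 1092 in the fit over all groups, where the spread is shared with the other lineages, and 991 with the GC correction. Leaving out single libraries gave 41 to 425 genes in endoderm and 718 to 1871 in the endoderm to ectoderm interaction. Replicate numbers did not pair the samples: correlations of same-numbered libraries were -0.03, 0.13 and -0.04 in mesoderm, -0.01, -0.07 and 0.04 in ectoderm and -0.09, 0.05 and -0.33 in endoderm. With the replicate block the endoderm to ectoderm interaction gave 594 genes against 1070, and no other count moved by over 1.5 times. ZNF263 kept its side of the threshold except in endoderm with the GC correction (-0.37, adjusted p = 0.00795), where its adjusted p ranged from 0.00795 to 0.533 over 11 alternatives, all with a lower level in KO. With an estimated correlation 1 list passed in mesoderm, 4 in ectoderm and 0 in endoderm; with fry 23 passed in mesoderm and 5 in endoderm. Shared calls of mesoderm and ectoderm fell from 1090 to 37 with the 2-fold criterion, those of mesoderm and endoderm from 67 to 31 and those of ectoderm and endoderm from 98 to 24. With DESeq2 the latter pairs shared 133 and 195. Where no construction is named, the cause was not tested. What depth alone limits was not separated from spread: the endoderm simulation recovered 24% of 1.5-fold changes and the mesoderm simulation 78%.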

Other observations

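Tests of GC content, copy number and cell composition here were chosen after the results were seen; the counts of other splits were planned before, except the one with the GC correction, which was added after the data were seen.

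The balance of some gene lists differed between KO mesoderm and KO ectoderm. YAP targets rose for 8 of 17 members and fell for 2 in mesoderm. In ectoderm they fell for 11 of 20 and rose for 2 (camera adjusted p = 6.52e-05, adjusted p = 0.154 with an estimated correlation). ANKRD1, a YAP-responsive gene, rose from 1.19 ± 0.37 to 5.54 ± 0.59 CPM in mesoderm and fell from 15.1 ± 1.7 to 8.56 ± 0.87 CPM in ectoderm. Of 19 YAP targets, 9 had a more positive change in mesoderm and 2 in ectoderm. Clustered protocadherins rose for 12 of 50 members and fell for 7 in mesoderm, where the list did not pass camera (adjusted p = 0.286), and in ectoderm they fell for 27 of 53 and rose for 2. Of 52 protocadherins, 25 had a more positive change in mesoderm and 2 in ectoderm. The 2 genes TXNIP and ARRDC4, which encode arrestins that respond to glucose metabolites and were chosen after their values were seen, rose in KO mesoderm from 138 ± 15 to 695 ± 64.5 CPM and from 18.7 ± 2.48 to 122 ± 15.3 CPM. The BMP antagonist gene GREM1 fell in mesoderm from 154 ± 4.1 to 40.5 ± 2.6 CPM and in endoderm from 19.4 ± 2 to 6.94 ± 0.43 CPM. Among imprinted genes besides H19, CDKN1C rose 2.24-fold in mesoderm, IGF2 fell 1.64-fold in ectoderm and DLK1 fell 2.92-fold in endoderm, where it did not pass without KO replicate 1 (edgeR adjusted p up to 0.0607).

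The genes called in the same direction in all lineages form the first pattern. A copy-number change of segments would move neighbouring genes as well. Of 50 of these 51 genes (the naming rule leaves 1 out), 41 had no other shared gene of the same direction within 1 megabase. The 5 tested genes on each side of these 41 had median signed log2 changes of at most 0.01 in a lineage, where the 41 genes themselves had median sizes of 0.80 to 1.22. The upper quartiles of the neighbours were 0.07 in mesoderm, 0.08 in ectoderm and 0.04 in endoderm. These values argue against a segment that spans the neighbours for most of the 41. They cannot exclude one over some of them, or a change of a single gene that leaves its neighbours still. Genes with a shared neighbour had been set aside beforehand, which can lower the values. The remaining 9 lay in 4 clusters that moved together: RPL23AP53 with ZNF596, ZIC4 with ZIC1, ZNF841 with ZNF880 and ZNF528, and ELOVL2 with NEDD9. The clusters were singled out after their values were seen. A copy-number change of 1 segment over a cluster, as the whole cause, would change its members by the same fold in every lineage. It is argued against for ZIC4 and ZIC1, where the 4 log2 changes at 1 CPM or more in WT and KO ran from -1.91 to -0.97 and 95.5% of their variance lay beyond their SE. It is argued against for ZNF841, ZNF880 and ZNF528, where 7 such values ran from 0.50 to 1.08 with 76.4% of the variance beyond the SE, and the 7 genes between them had a median log2 change of 0.09. Separate segments for single genes of this cluster were not tested. For ELOVL2 and NEDD9 such a change and a shared regulation cannot be told apart: 0% of the variance of 5 values, from -0.67 to -0.56, lay beyond the SE. The sixth value, ELOVL2 in mesoderm, was -1.52 (SE 0.453) but lay under 1 CPM and was left out. The 1 gene between them with values at 1 CPM or more did not move with them (median 0.03 in the other direction) but is too little to decide. For RPL23AP53 and ZNF596 they cannot be told apart either, since 0 values lay at 1 CPM or more in both genotypes and a loss of the segment in WT would leave counts near 0 there as well. A GC trend is argued against too, since 50 of the 50 genes were still called the same way in every lineage after GC correction. Loss of ZNF263 and another difference of the edited line cannot be told apart, because the labels name 1 edited line.

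The second pattern is the shift in KO ectoderm. After GC correction 19 of 19 pluripotency genes were still called higher and 24 of 24 neuroectoderm genes lower, which argues against a GC trend. The log2 changes of the 32 neuroectoderm genes ran from -1.76 to 1.49, 3 members rose, and 99.0% of their variance lay beyond their SE. The genes thus did not fall by 1 fold, but this does not decide whether a lower share of neuroectoderm cells was the cause. Such a share would give 1 fold only for genes that the other cells do not express, and SOX2 is in the pluripotency list as well. For the pluripotency genes, undifferentiated cells left in the KO ectoderm and a change in gene regulation within the ectoderm cells cannot be told apart. Of the 8 members under 5 CPM in WT, 100% were called higher, but 7 of them lay under 1 CPM in WT, where a gene can hardly be called lower, so this share decides nothing. The 17 others were already at 5 CPM or more in WT ectoderm.

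The third pattern is the low number of calls in endoderm. The libraries differed along GC content: between genes at the 10th and 90th GC percentile (38.7% and 61.8%) the log2 level shifted by 0.50 in WT replicate 1 and by -0.41 in WT replicate 3, against -0.18 to 0.16 in KO. The GC correction lowered the biological coefficient of variation from 13.5% to 8.48%, but also from 7.29% to 4.67% in mesoderm and from 4.01% to 2.79% in ectoderm, so the fall was not particular to endoderm. It raised the calls from 179 to 991, far below the 7839 and 7723 genes called with it in mesoderm and ectoderm. A GC trend as the whole cause of the low number is therefore argued against, and its part in it stays open. WT replicate 2, in which 22098 genes were detected at a common depth against 19318 to 20168 in the other endoderm libraries, is argued against as the cause, because the coefficient was 15% without it. The coefficient was 9.33% without WT replicate 1, with 425 calls, and 10.5% without WT replicate 3, with 173 calls. It was 14.5% to 15.3% without any 1 of the other endoderm libraries. WT replicates 1 and 3 thus added to the spread, but their part in the low number of calls stays open.

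With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split gave 6328 genes in mesoderm and 6188 in ectoderm and 12630 between WT mesoderm and WT ectoderm, and the highest other split gave 0 in each. In endoderm the real split gave 179 and the highest other 1, and with GC correction 991 and 1. In each of these comparisons 1 split, the real one, reached the real number. A split that mixes the groups puts their real difference into the spread, so its count tends to be low where the groups differ. The counts of 0 and 1 are therefore no separate support for the real numbers.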
